A study of Arabidopsis thaliana with 60 samples.

How the data were processed

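The study measured whole 7-day seedlings of Arabidopsis thaliana Col-0 with Affymetrix ATH1 arrays, per the labels, after 3 h or 12 h with a compound or a mock treatment, with 2 arrays in each of 30 groups. The values are probe set intensity values on a linear scale, made by the authors with MAS5 per the submitters' processing notes; its version and target are not given in the sources used here. The table held 22810 probe sets with intensities from 0.2 to 66000.6, and 64 control probe sets were left out. Every column matched 1 sample. The 2% trimmed mean of the deposited intensities was the same for all arrays of 1 replicate number in 1 bracket, and differed between these 6 scaling sets: 1523 and 1219 in F1, 1019 and 1441 in F2, and 1359 and 1266 in G for replicates 1 and 2. The sets were therefore treated as a processing batch, which every comparison within a bracket crosses evenly. Within a set a group has 1 array, so there the comparison is of 1 array with 1 array.

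Intensities were transformed as log2(value + 133.4), the pseudocount being the median over arrays of the 20th percentile, so a fold change understates the change of dim probe sets. Probe sets above their array's 40th percentile on at least 2 arrays were kept, 17301 of 22746. No other normalization was applied, because MAS5 scales each array. limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 60 arrays, with 30 residual degrees of freedom and an intensity trend in the variance prior, and p-values were adjusted by the Benjamini-Hochberg method within each comparison with a threshold of 0.05. The fit with the scaling set as a block had 27 residual degrees of freedom. The median residual SD was 0.312 log2 units without the block and 0.209 with it. Comparisons were each treated group against the mock of its bracket, related compounds against each other, responses at 12 h against 3 h, responses at different doses, and the mocks. The tests, the comparisons, the gene lists, the naming rule and all alternatives other than the rescaling to a common trimmed mean were chosen before the data were examined; giving the blocked values beside each result, and naming genes from them, was chosen after the scaling sets had been seen.

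Gene names came from a probe table of the platform annotation, which is old: 13513 probe sets named exactly 1 gene, 503 several and 8730 were not listed. Of the former 13436 matched the TAIR10.1 gene table, used for names only. Genes known only by locus are named more often than genes with a symbol: 63.1% against 14.6% of protein-coding genes. No gene was named from a probe set with several genes, and 9601 kept probe sets named 1 gene. Where a gene had several probe sets, the brightest was used in lists; for CHX 1 of 4919 called genes had probe sets called in opposite directions. Genes named in the text are the 5 highest and 5 lowest called genes of each compound (3 and 3 for other comparisons) whose treated arrays both lie beyond both mock arrays, called members of the lists assigned to the compound and the 2 members with the largest change, and genes called in all of the 5 related compounds, the same rule being applied to calls with the block; some were left out for space.

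Of 34 gene lists with 647 members, 114 members were measured, 29 lists had at least 1 and 17 at least 3. Shifts of the 29 lists in 27 comparisons (783 tests, adjusted together) were tested two-sided with camera of limma and the correlation estimated from the data: 33 passed, and all 33 also passed with a preset correlation of 0.01, where 103 passed; 27 passed with the block. Of these, 11 of the 33, and 3 of the 27 with the block, are lists with 1 measured member, so they rest on 1 gene and are not reported as list shifts. The preset correlation is the laxer setting here, so passing with it adds no support to the 33. Intervals are 95% intervals. Covariances of fold changes between related compounds were set beside 50 simulations of unchanged groups that shared mock arrays in the same way. All simulated arrays, the mocks included, were drawn with normal noise independent between probe sets.

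The fit was tested on simulated data for propiconazole at 3 h with 17301 probe sets. Without the block it recovered 15% of changes of log2 size 1 and 100% of size 2, with 0 false calls; with the block it recovered 80% and 100%, with 4 false calls among 184. camera found the list that had been shifted, and 0 of 28 unshifted lists had p under 0.05. Replicates of a group correlated with r between 0.959 and 0.982 over probe sets. The ratio of 3′ to 5′ probe sets lay between 1.22 and 1.89 for actin (median 1.49) and between 0.824 and 1.26 for GAPDH. Alternatives were quantile normalization, no pseudocount, no filter, the block, arrays of the bracket alone, both 3 h mocks as the control, a preset correlation, each array left out in turn and the rescaling. The fits with 1 array left out had no block, so a comparison that lost an array crossed the scaling sets unevenly. No coordinates are given, since no genome build was used.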

Results

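Gene expression was measured on Affymetrix ATH1 arrays in whole 7-day Arabidopsis seedlings of the accession Col-0, kept in liquid medium with a compound or with a mock treatment. There were 60 arrays in 30 groups of 2: 27 treated groups, covering 18 compounds, and 3 mock groups. The labels sort the groups into brackets, each with its own mock: F1 (3 h, 18 treated groups), F2 (12 h, 7 treated groups) and G (3 h, 2 treated groups). Each treated group was compared with the mock of its bracket. The labels do not say whether the arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. Differences are given as log2 difference ± SE with n = 2 arrays per group, and p-values are adjusted over 17301 probe sets. The deposited values fall into 6 scaling sets (the arrays of 1 replicate number in 1 bracket), each at its own level, and values with the scaling set as a block are given as "with the block"; log2 differences are the same in both fits, and a value said to pass only with the block carries the SE of that fit. The number of arrays limits the precision: the median 95% interval reached 0.63 log2 units to either side of a difference without the block and 0.42 with it. Counts of probe sets at unadjusted p under 0.05 are given beside low counts of calls. With no change, a share of 0.05 of the 17301 probe sets would have such a p. A count below that share is no sign of a response beneath the threshold. The ratio of 3′ to 5′ actin probe sets, a sign of RNA quality, lay between 1.22 and 1.89, and its highest value belonged to replicate 1 of the F1 mock, which enters 18 of the comparisons.

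**Figure D1:**
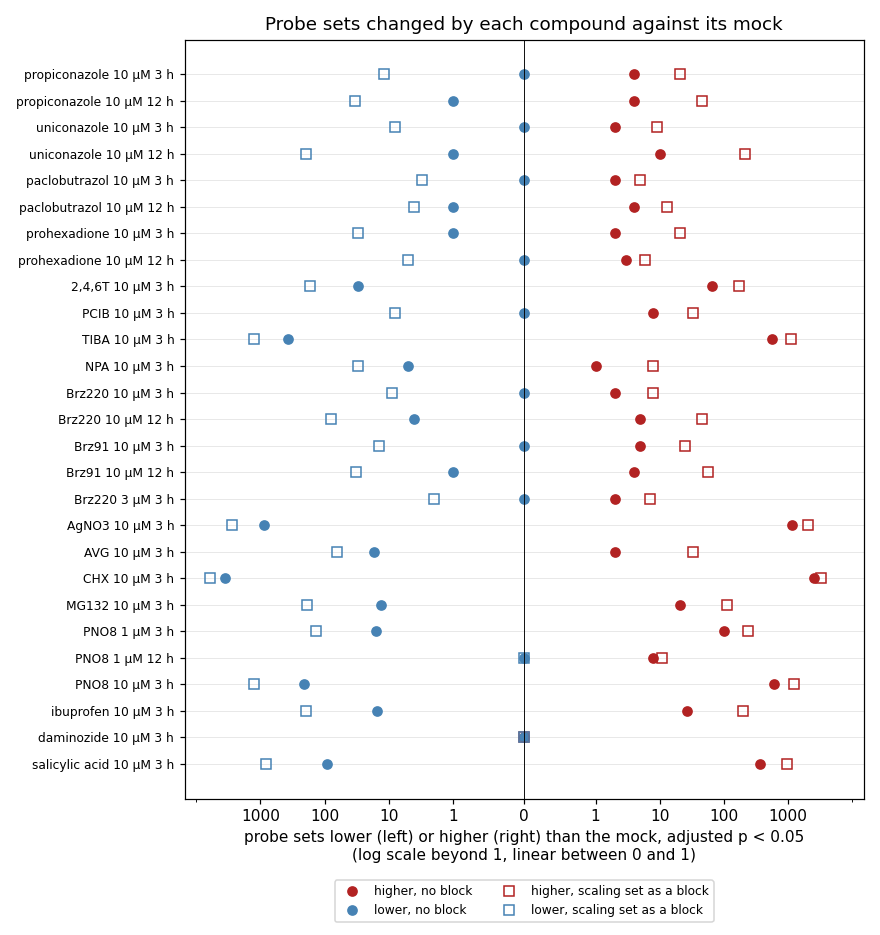
Number of probe sets lower (left) or higher (right) than the mock at adjusted p under 0.05 for each compound, dose and time, on an axis that is logarithmic beyond 1 and linear between 0 and 1. Filled circles are counts without a block and open squares are counts with the scaling set as a block; cycloheximide (CHX) had 6135 without the block, and daminozide had 0 in both.

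The first question was what propiconazole, uniconazole and paclobutrazol, which carry a triazole ring, and the code-named compounds Brz220 and Brz91 do at 10 µM. At 12 h AT5G01740 rose with all 5 compounds, by 2.16 ± 0.31 with propiconazole, 2.18 ± 0.31 with uniconazole, 1.92 ± 0.31 with paclobutrazol, 2.096 ± 0.31 with Brz220 and 1.92 ± 0.31 with Brz91 (adjusted p between 9.58e-06 and 0.00067). AT1G29660, which encodes a GDSL-type esterase/lipase, fell with all 5, with differences of -2.82 ± 0.33, -2.71 ± 0.33, -2.01 ± 0.33, -2.98 ± 0.33 and -2.33 ± 0.33 in the same order (adjusted p between 1.65e-08 and 0.00067). These were the named genes among 4 probe sets called in all 5 at 12 h. With the block 13 were called in all 5; their named genes also included FDH (formate dehydrogenase), with differences of 0.70 to 1.12, AT5G22580 and AT5G57785 on the higher side, and CSLC04, a xyloglucan glucan synthase, with differences of -0.81 to -0.66, and AT4G29020 on the lower side. EXPA8, an expansin, fell by 1.88 ± 0.34 with Brz220 at 12 h (adjusted p = 0.00349; 0.000218 with the block), as did AT4G18970 by 1.70 ± 0.36 (adjusted p = 0.026).

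**Figure D2:**
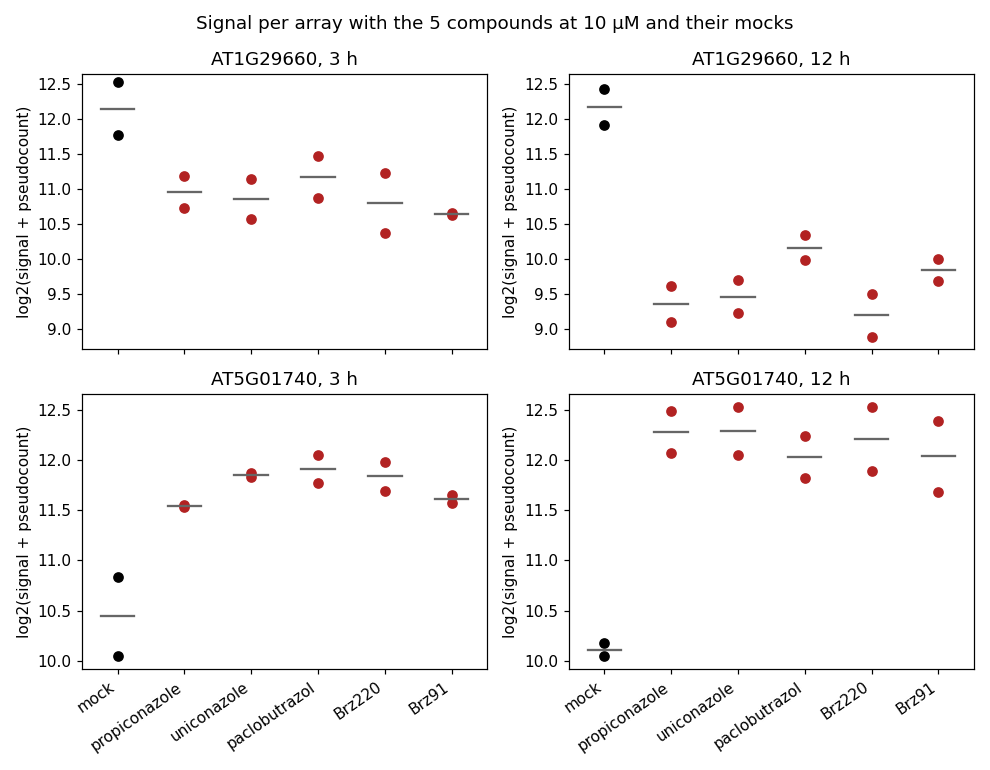
log2(signal + pseudocount) of AT1G29660 and AT5G01740 on each array at 3 h (left) and 12 h (right), in the mock (black) and with 5 compounds at 10 µM (red); each point is 1 array and each line the mean of 2. At 12 h AT1G29660 averaged 12.18 in the mock and AT5G01740 was higher with each compound than on both mock arrays.

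At 3 h AT1G47400, which encodes an iron-deficiency peptide, rose by 2.197 ± 0.34 with propiconazole (adjusted p = 0.000146) and by 2.29 ± 0.34 with Brz91 (5.21e-05). AT2G33490 rose by 1.60 ± 0.31 with uniconazole (adjusted p = 0.0276), 1.59 ± 0.31 with paclobutrazol (0.0306) and 1.57 ± 0.31 with Brz220 (0.0397). Its level in the F1 mock, 8.07, was also below the 9.45 of the G mock, which had no compound. With the block AT2G33490 was higher in 16 of the 18 comparisons with the F1 mock, and the lowest treated group of that bracket stood at 8.98. Its rise is thus not particular to these compounds. AT5G01740 and AT1G29660 passed the threshold in all 5 only with the block, with AT5G01740 between 1.0999 and 1.47 and AT1G29660 between -1.52 and -0.99. AT1G29660 was also lower in the G mock than in the F1 mock, by -0.64 (adjusted p = 0.0303 with the block). With the block it was lower in 10 of the 18 comparisons with the F1 mock, and it stood at -1.995 with TIBA and -1.59 with NPA. Its fall at 3 h is thus not particular to the 5 compounds either. With Brz220 at 3 µM, tested in bracket G, limma called 2 probe sets, both higher and without a gene name (219 at unadjusted p under 0.05), and 0 lower. With the block PRN (1.29 ± 0.22, adjusted p = 0.00444) and AT4G36700 (-1.77 ± 0.34, adjusted p = 0.0164) passed, among 7 higher and 2 lower; quantile normalization gave 5 and 1. Leaving out replicate 1 of the G mock took the 2 calls to 0.

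Of the lists fixed for these compounds, cell wall expansion (expansins and xyloglucan endotransglucosylases, 12 members measured) lay lower at 12 h with the block: the camera adjusted p with an estimated correlation was 0.00369 for propiconazole, 0.00681 for uniconazole, 0.00101 for paclobutrazol, 0.000387 for Brz220 and 0.00681 for Brz91. Without the block the adjusted p was 0.273, 0.302, 0.186, 0.0743 and 0.305 with an estimated correlation. Of the 12 members limma called 0, 0, 0, 1 (EXPA8) and 0 without the block in the same order (3, 4, 4, 5 and 4 at unadjusted p under 0.05), and 2, 3, 0, 4 (EXPA8, XTH19, XTH33 and XTH18) and 0 with the block. Adjusted over the list alone, 3, 3, 3, 4 and 0 were lower, and 6, 6, 4, 7 and 5 with the block. Members with the block were XTH16 at -1.19 ± 0.20 for uniconazole (adjusted p = 0.000665) and XTH19 at -1.54 ± 0.29 for Brz220 (adjusted p = 0.00317). EXPA8 was also the only measured member of the list of gibberellin-induced genes, and its own test with the block gave adjusted p = 0.00718 for propiconazole and 0.0126 for uniconazole at 12 h. In neither fit was it called at 12 h with paclobutrazol (-0.551), Brz91 (-0.659) or prohexadione (-0.566). With the block it was also lower at 3 h with PNO8 at 10 µM (-2.69), CHX (-1.56), NPA (-1.55), TIBA (-1.53), ibuprofen (-1.49) and AgNO3 (-1.31). Its fall was thus not particular to the 5 compounds. EXO, the only measured member of the brassinosteroid-induced list, had negative values with all 5 compounds at both times, from -0.68 with paclobutrazol at 3 h to -0.25 with Brz91 at 12 h. With these 5 compounds none passed over all probe sets in either fit. A lower value at 3 h was not particular to them. EXO stood at -0.806 with AgNO3 and -0.768 with PNO8 at 1 µM, which both passed with the block, and at -0.68 with ibuprofen. It had positive values at 3 h with CHX (2.54), AVG (0.576) and PNO8 at 10 µM (0.161). This list has 1 measured member, so adjustment over the list alone leaves its p-values unadjusted. At unadjusted p under 0.05 EXO was lower with propiconazole and paclobutrazol at 3 h and Brz220 at 12 h. With the block this held at both times with propiconazole, uniconazole, paclobutrazol and Brz220. With Brz220 at 3 µM the cell wall expansion list had adjusted p = 0.664 with an estimated correlation and 0.0358 with the block. At 10 µM and 3 h the list did not pass with any of the 5 compounds, Brz220 included, in either fit. Of 7 measured gibberellin-repressed genes limma called 0 with each of the 5 compounds at 12 h, over all probe sets, with the block and adjusted over the list alone. At unadjusted p under 0.05 there were 0 with each without the block, and 1, 2, 0, 0 and 0 with the block for propiconazole, uniconazole, paclobutrazol, Brz220 and Brz91. The 7, of 15 in the list, were GID1A, GID1B, GID1C, XERICO, AT5G50915, AT2G31730 and IQD22. The GA20ox, GA3ox and SCL3 genes of the list were not measured, nor was any of 7 listed brassinosteroid biosynthesis genes. The calls of 0 therefore say nothing about those genes.

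limma called 4 higher and 0 lower probe sets with propiconazole at 3 h (21 and 12 with the block; 12 and 4 after quantile normalization) and 4 and 1 at 12 h (45 and 34; 29 and 22). For uniconazole it called 2 and 0 at 3 h (9 and 8; 5 and 5) and 10 and 1 at 12 h (212 and 197; 108 and 105). Paclobutrazol gave 2 and 0 at 3 h (5 and 3 with the block) and 4 and 1 at 12 h (13 and 4). Brz220 gave 2 and 0 at 3 h (8 and 9; 7 and 7) and 5 and 4 at 12 h (46 and 79; 32 and 46), and Brz91 gave 5 and 0 at 3 h (25 and 14; 19 and 8) and 4 and 1 at 12 h (57 and 32; 27 and 12). The counts of 0 stand beside 452, 389, 287, 350 and 399 probe sets at unadjusted p under 0.05 for propiconazole, uniconazole, paclobutrazol, Brz220 and Brz91 at 3 h. With the block there were 1751, 1509, 1006, 1346 and 1549 in the same order. No change would leave a share of 0.05 of the 17301 probe sets at such a p. Each count without the block lies below that share, and each with the block above it. The counts without the block therefore show no response beneath the threshold, and calls of 0 there do not show its absence. At 12 h uniconazole went from 11 to 3 and paclobutrazol from 5 to 1 without replicate 1 of the mock, Brz91 from 5 to 3 without its replicate 2, propiconazole from 5 to 3 without replicate 2 of propiconazole and Brz220 from 9 to 2 without replicate 2 of Brz220. At 3 h each compound went to 1: uniconazole and Brz220 without replicate 1 of the mock, paclobutrazol and Brz91 without its replicate 2, and propiconazole without replicate 1 of propiconazole.

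The related compounds were also set directly against each other at matched dose and time. For propiconazole minus uniconazole limma called 0 probe sets at 3 h and 0 at 12 h (93 and 283 at unadjusted p under 0.05), for propiconazole minus paclobutrazol 0 and 0 (268 and 127), for uniconazole minus paclobutrazol 0 and 0 (139 and 239) and for Brz220 minus Brz91 0 and 0 (205 and 139). After quantile normalization it called 1 for propiconazole minus paclobutrazol at each time, and 1 for uniconazole minus paclobutrazol and 1 for Brz220 minus Brz91 at 12 h. Uniconazole has a carbon-carbon double bond where paclobutrazol has a single bond: their 12 h difference with the block was 0.26 (95% interval -0.17 to 0.69) for AT5G01740 and -0.70 (-1.09 to -0.31, adjusted p = 0.307) for AT1G29660. AT1G29660 was also lower with propiconazole than with paclobutrazol, by -0.81 (95% interval -1.19 to -0.42, adjusted p = 0.495), and with Brz220 than with Brz91, by -0.65 (-1.04 to -0.27, adjusted p = 0.999); none of these passed the correction. Between propiconazole and uniconazole at 12 h the interval was -0.49 to 0.28 for AT1G29660 and -0.44 to 0.41 for AT5G01740. For FDH at 12 h the difference was -0.42 (95% interval -0.67 to -0.17, adjusted p = 0.491) between propiconazole and uniconazole and 0.32 (0.08 to 0.57, adjusted p = 0.605) between uniconazole and paclobutrazol. The interval also left out 0 for AT4G19860 between propiconazole and uniconazole, and for AT5G45670, AT4G18970 and AT1G21680 between Brz220 and Brz91. None of these passed the correction. With the block SWEET16, a vacuolar sugar transporter, was lower with propiconazole than with paclobutrazol at 3 h (-1.18 ± 0.21, adjusted p = 0.0404) and AT2G43550 lower with uniconazole than with paclobutrazol at 12 h (-0.90 ± 0.15, adjusted p = 0.015). Without replicate 2 of uniconazole at 12 h limma called 2 for propiconazole minus uniconazole and 4 for uniconazole minus paclobutrazol.

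Pairs of these 5 compounds shared between 1 and 4 higher probe sets at each time, and 1 lower probe set at 12 h. With the block they shared 5 to 15 higher and 1 to 5 lower at 3 h, and 11 to 47 higher and 3 to 43 lower at 12 h. The covariance of fold changes ran from 0.0372 for paclobutrazol and Brz91 at 3 h to 0.0556 for uniconazole and Brz91 at 12 h. In 50 simulations of unchanged groups against shared mock arrays it was 0.0276 on average for both pairs. The simulated mock arrays were drawn anew, with noise independent between probe sets. Any particular deviation of the real mock arrays is therefore not in this value, and the excess over it cannot be told apart from such a deviation. A bracket has only 2 mock arrays, which cannot be split, so part of the shared calls may come from the shared mock.

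Prohexadione and daminozide, inhibitors of gibberellin biosynthesis, were given at 10 µM. With prohexadione AT1G19960 rose by 2.05 ± 0.36 at 3 h (adjusted p = 0.00389) and by 2.32 ± 0.36 at 12 h (0.000455). With the block AT5G03350, a legume-lectin family gene, stood at 1.98 ± 0.47 (adjusted p = 0.0464), OTP81 at -1.39 ± 0.22 (0.000937) and AT4G21870 at -1.31 ± 0.19 (0.000197) at 3 h. The 6 measured genes of the flavonoid pathway had 0 calls by limma with prohexadione at 3 h and at 12 h (0 and 1 at unadjusted p under 0.05). limma called 2 higher and 1 lower at 3 h (21 and 30 with the block; 10 and 14 after quantile normalization) and 3 and 0 at 12 h (6 and 5; 6 and 4), where 276 had unadjusted p under 0.05. With daminozide at 3 h limma called 0 probe sets, and 0 with the block, where 350 and 1555 had unadjusted p under 0.05. Leaving out replicate 2 of the F1 mock took prohexadione at 3 h from 3 to 0, and leaving out replicate 2 of the F2 mock took 3 to 0 at 12 h. Daminozide had 1 without replicate 1 of daminozide.

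The compounds 2,4,6T and PCIB were given at 10 µM for 3 h. With 2,4,6T the glutathione transferases GSTU25 (3.28 ± 0.40, adjusted p = 1.47e-07) and GSTU22 (2.15 ± 0.32, 8.96e-06), the auxin-conjugating enzyme GH3.3 (2.24 ± 0.36, 4.71e-05) and AT3G07720 (2.48 ± 0.34, 1.89e-06) rose. The peroxidase genes AT1G34510 (-2.36 ± 0.40, adjusted p = 0.000146) and AT4G26010 (-1.82 ± 0.36, 0.00223) and the root hair expansin EXPA18 (-1.60 ± 0.35, 0.00777) fell. With PCIB GSTU22 rose by 1.75 ± 0.32 (adjusted p = 0.0048), AT4G38410 by 1.55 ± 0.32 (0.0254) and AT4G13180 by 1.396 ± 0.27 (0.00988). Of 8 measured detoxification genes 3 rose with 2,4,6T (4 adjusted over the list alone) and 1 with PCIB (2 adjusted over the list alone), and the list shifted up with adjusted p = 0.00106 and 0.0133 (0.00681 and 0.0358 with the block). For PCIB it was 0.362 without replicate 2 of PCIB. Of 9 measured auxin response genes 1 rose with 2,4,6T, which was GH3.3 (2 adjusted over the list alone). With PCIB limma called 0 (3 at unadjusted p under 0.05; 1 adjusted over the list alone), and GH3.3 passed with the block (1.54 ± 0.34, adjusted p = 0.0316). The salicylate list shifted up with 2,4,6T (adjusted p = 0.0268; 0.0678 with the block), and 1 of its 3 members rose. In turn 1 of the 2 root hair markers fell (2 adjusted over the list alone; list adjusted p = 0.0123, 0.0622 with the block). These lists had adjusted p = 0.235 for salicylate without replicate 2 of 2,4,6T and 0.253 for root hair markers without its replicate 1.

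limma called 66 higher and 30 lower probe sets with 2,4,6T (175 and 169 with the block; 153 and 138 after quantile normalization) and 8 and 0 with PCIB (33 and 8; 27 and 6), for which 344 had unadjusted p under 0.05. Directly compared, AT1G72800 (1.79 ± 0.30, adjusted p = 0.00324), AT1G30700 (1.73 ± 0.33, 0.0149) and AT4G01870 (1.90 ± 0.40, 0.0354) were higher with 2,4,6T than with PCIB, and AT5G03350 (-1.999 ± 0.44, 0.0456), AT1G34510 (-1.90 ± 0.40, 0.0354) and AT1G30870 (-1.68 ± 0.36, 0.0354) were lower, among 5 higher and 7 lower (27 and 44 with the block). For GH3.3 the difference was 0.70 (95% interval with the block 0.02 to 1.39, adjusted p = 0.778) and for GSTU22 0.41 (-0.16 to 0.97, adjusted p = 0.939). Leaving out replicate 1 of 2,4,6T took 96 calls to 30 and the 12 direct calls to 0, and leaving out replicate 2 of the F1 mock took the 8 of PCIB to 0.

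TIBA and NPA, inhibitors of auxin transport, were given at 10 µM for 3 h. GH3.3 rose with both, by 4.82 ± 0.36 with TIBA (adjusted p = 3.5e-16) and 2.98 ± 0.36 with NPA (3.46e-07). With TIBA GSTU25 (4.73 ± 0.40, adjusted p = 3.72e-14), the glycosyltransferase genes UGT73B4 (4.08 ± 0.40) and UGT73B5 (3.80 ± 0.33), the small heat shock protein gene AT2G29500 (4.33 ± 0.42) and the transcription factor genes WRKY6 (2.46 ± 0.31) and STZ (2.45 ± 0.30) also rose. The peroxidase genes AT1G34510 (-4.50 ± 0.40, adjusted p = 1.41e-13) and AT3G49960 (-4.44 ± 0.42), XTH26 (-3.46 ± 0.37), EXPA18 (-2.37 ± 0.35) and EXPA7 (-1.77 ± 0.32) fell. With NPA AT5G04120 (-2.01 ± 0.37, adjusted p = 0.00724) and AT1G29660 (-1.59 ± 0.33, 0.0364) fell.

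In the lists, 6 of 8 detoxification genes, 4 of 5 heat shock genes, 3 of 4 early stress genes and 3 of 3 oxidative stress genes rose with TIBA, and 6, 5, 3 and 3 did adjusted over the list alone. Their camera adjusted p was 0.000215, 0.00996, 0.0148 and 0.00105 (0.00203, 0.0357, 0.0678 and 0.00708 with the block). For early stress it was 0.0665 without replicate 1 of the F1 mock. Both measured root hair markers fell with TIBA, and 4 of 12 cell wall expansion genes did (EXPA8, EXPB1, XTH16 and XTH33; 5 adjusted over the list alone). Of the 9 auxin response genes GH3.3 alone rose with TIBA without the block (1 adjusted over the list alone), while 3 passed with the block, and with NPA GH3.3 alone rose in both fits. limma called 556 higher and 377 lower probe sets with TIBA (1122 and 1265 with the block; 1048 and 1137 after quantile normalization) and 1 and 5 with NPA (8 and 30 with the block).

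Directly compared, GSTU25 (4.51 ± 0.40, adjusted p = 2.62e-13), UGT73B4 (4.35 ± 0.40) and AT4G37290 (4.15 ± 0.38) were higher with TIBA than with NPA, and AT3G49960 (-4.14 ± 0.42) and AT1G34510 (-4.09 ± 0.40) lower. GH3.3 was higher with TIBA by 1.84 (95% interval with the block 1.16 to 2.53, adjusted p = 0.000107 with the block), and EXPA8 differed by 0.02 (-0.59 to 0.62). The direct comparison had 553 higher and 239 lower probe sets (1045 and 959 with the block; 910 and 777 after quantile normalization). Without replicate 1 of the F1 mock TIBA went from 933 to 600 and NPA from 6 to 1, and leaving out replicate 1 of TIBA took the direct count from 792 to 494.

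Silver nitrate (AgNO3), which blocks ethylene perception, and AVG, an inhibitor of ethylene biosynthesis, were given at 10 µM for 3 h. With AgNO3 AT1G26380 (5.71 ± 0.46, adjusted p = 1.95e-15) and AT1G26420 (4.48 ± 0.33), of the berberine bridge enzyme family, AT3G23550 (5.03 ± 0.37), WRKY6 (2.95 ± 0.31), STZ (2.82 ± 0.30) and WRKY53 (1.90 ± 0.29) rose. The peroxidase genes AT3G49960 (-4.55 ± 0.42, adjusted p = 4.46e-13) and AT1G34510 (-4.01 ± 0.40) and the root hair expansins EXPA18 (-2.60 ± 0.35) and EXPA7 (-1.83 ± 0.32) fell, as did the metallothionein gene MT1C (-1.07 ± 0.30, 0.00853). With AVG GH3.3 (-2.38 ± 0.36, adjusted p = 5.5e-05), AT2G39980 (-2.09 ± 0.36, 0.000559), AT5G62280 (-2.08 ± 0.33, 0.000123) and the ARGOS-like gene ARL (-1.41 ± 0.31, 0.026) fell, and AT5G04120 rose (2.13 ± 0.37, 0.000605).

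All 4 measured early stress genes rose with AgNO3 (4 adjusted over the list alone; list adjusted p = 0.00476, 0.0358 with the block). Of 8 detoxification genes 3 rose and 1, GSTU18, fell (5 and 1 adjusted over the list alone). Of the 9 auxin response genes 2 fell with AVG (4 adjusted over the list alone), and the list shifted down (adjusted p = 0.00291, and 0.000542 with the block). Of 18 genes in the ethylene response list only ARL, RTE1 and PDF1.2 were measured. ERS1, ERS2, ETR2, EBF2 and ERF1 were not, so counts in this list say little about ethylene responses. Of the 3 measured ethylene response genes 1 fell with AVG (1 adjusted over the list alone; list adjusted p = 0.0176, 0.0358 with the block and 0.14 without replicate 1 of the F1 mock), and limma called 0 with AgNO3 (0 at unadjusted p under 0.05). limma called 1173 higher and 889 lower probe sets with AgNO3 (2020 and 2745 with the block; 1873 and 2414 after rescaling to a common trimmed mean) around a median of all probe sets of -0.109, and 2 and 17 with AVG (33 and 64; 21 and 36 after quantile normalization). Leaving out replicate 1 of AgNO3, whose actin ratio of 1.83 was among the highest, took 2062 to 1149, and leaving out replicate 1 of the F1 mock took AVG from 19 to 4.

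Cycloheximide (CHX), which blocks translation, changed more probe sets at 10 µM and 3 h than any other treatment. AT5G64870, a flotillin-like gene (7.13 ± 0.35, adjusted p = 6.66e-26), AT3G01830 (6.91 ± 0.33), WRKY53 (6.27 ± 0.29), STZ (5.48 ± 0.30), OPCL1, an enzyme of jasmonate synthesis (4.95 ± 0.30), GH3.3 (4.93 ± 0.36) and GH3.1 (4.57 ± 0.38) rose. AT5G48490 (-4.20 ± 0.32, adjusted p = 1.74e-17), AT4G11190 (-3.99 ± 0.37) and the methionine sulfoxide reductase gene MSRB5 (-3.94 ± 0.42) fell. All 4 early stress genes rose (4 adjusted over the list alone; list adjusted p = 0.00301, 0.0357 with the block) and 8 of 9 auxin response genes did (8 adjusted over the list alone; list adjusted p = 0.0505 with an estimated correlation, 0.00555 with the block). Of 12 cell wall expansion genes 4 rose, with XTH18 at 4.40 ± 0.39, and 2 fell (4 and 2 adjusted over the list alone). Of 4 measured cytosolic ribosomal protein genes 1 fell (AT2G19730, -0.84 ± 0.32, adjusted p = 0.0349; 1 adjusted over the list alone). limma called 2535 higher and 3600 lower probe sets (3271 and 6154 with the block), around a median of all probe sets of -0.214. The 6135 became 3988 without replicate 1 of the F1 mock.

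MG132, a proteasome inhibitor, was given at 10 µM for 3 h. GSTU25 (2.92 ± 0.40, adjusted p = 3.68e-06), AT5G51440, a small heat shock protein gene (2.51 ± 0.37, 2.52e-05), AT1G47400 (2.46 ± 0.34, 3.68e-06) and GSTU22 (1.82 ± 0.32, 0.000981) rose. AT1G34510 (-2.01 ± 0.40, adjusted p = 0.00588), AT2G37750 (-1.95 ± 0.37, 0.00243) and SWEET16 (-1.46 ± 0.33, 0.0281) fell. All 8 measured proteasome subunit genes had positive values, with a median of 0.44; with the block 4 of them passed, among them AT5G23540 (0.68 ± 0.13, adjusted p = 0.00185) and AT1G04810 (0.62 ± 0.13, 0.00461), and 5 did with the block adjusted over the list alone. Without the block limma called 0 of the 8 (2 at unadjusted p under 0.05). The list had adjusted p = 0.604 with an estimated correlation, and 0.0358 with the block. The oxidative stress list shifted up (adjusted p = 0.0133; 0.0704 with the block, 0.258 without replicate 1 of the F1 mock), and 1 of its 3 members rose (2 adjusted over the list alone). limma called 21 higher and 13 lower (110 and 190 with the block; 63 and 100 after quantile normalization), and 8 in all without replicate 1 of the F1 mock against 61 without its replicate 2.

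The compound PNO8 was given at 1 µM for 3 h and 12 h and at 10 µM for 3 h. At 1 µM and 3 h GSTU25 (4.59 ± 0.40, adjusted p = 1.64e-12), AT4G01870 (3.38 ± 0.40, 1.35e-08), GSTU22 (2.71 ± 0.32), AT1G47400 (2.61 ± 0.34) and UGT73B4 (2.54 ± 0.40) rose. AT2G25150 (-1.51 ± 0.39, 0.0401) fell. At 12 h the small heat shock protein genes AT1G53540 (3.198 ± 0.37, adjusted p = 5.22e-08) and AT2G29500 (2.25 ± 0.42, 0.00416) rose. At 10 µM UGT73B5 (4.80 ± 0.33, adjusted p = 5.78e-18), AT1G26380 (4.299 ± 0.46), GSTU25 (3.95 ± 0.40) and the mitochondrial stress gene AT2G21640 (2.75 ± 0.40) rose. AT1G34510 (-3.12 ± 0.40, 1.91e-08), EXPA8 (-2.69 ± 0.34) and EXPA18 (-2.14 ± 0.35) fell. Of 8 detoxification genes 4 rose at 1 µM and 3 h (5 adjusted over the list alone; list adjusted p = 1.98e-05, 0.000387 with the block) and 6 at 10 µM (6 adjusted over the list alone; 0.000838, 0.00681 with the block). At 10 µM the 4 early stress genes (list adjusted p = 0.000603; 0.00681 with the block) and the 3 oxidative stress genes (0.00996; 0.0395 with the block) all rose. Fitted on the arrays of bracket G alone, the list adjusted p at 10 µM was 0.22 for detoxification, 0.491 for early stress and 0.276 for oxidative stress, and after quantile normalization it was 0.091 for oxidative stress. At 12 h 1 of 5 heat shock genes rose (2 adjusted over the list alone; list adjusted p = 0.00735, 0.0589 with the block and 0.43 without replicate 2 of PNO8). Of the 9 measured photosynthesis genes limma called 0 at 1 µM and 0 at 10 µM at 3 h (1 and 0 at unadjusted p under 0.05, and 1 and 0 adjusted over the list alone). LHCB4.3 passed with the block at 1 µM (1.23 ± 0.19, adjusted p = 4.38e-05), as it did at 3 h with propiconazole (1.08 ± 0.19, 0.00479) and Brz91 (1.25 ± 0.19, 0.000272).

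limma called 101 higher and 16 lower probe sets with PNO8 at 1 µM and 3 h (242 and 137 with the block; 198 and 101 after quantile normalization), 8 and 0 at 12 h (11 and 0 with the block), where 272 had unadjusted p under 0.05, and 601 and 207 at 10 µM (1236 and 1271; 1157 and 1225). Each dose was set against its own mock, in brackets F1 and G. The response at 10 µM exceeded that at 1 µM for AT1G09500 by 3.17 ± 0.47 (adjusted p = 1.76e-05) and for AT5G16980 by 2.98 ± 0.47 (5e-05), and was lower for AT5G62210 by -2.69 ± 0.57 (0.00506) and for AT1G34510 by -2.22 ± 0.57 (0.039). In all 103 probe sets differed upward and 18 downward (331 and 194 with the block; 332 and 171 after quantile normalization). For Brz220 at 10 µM against 3 µM limma called 0, and 0 with the block (230 and 885 at unadjusted p under 0.05). Leaving out replicate 2 of PNO8 took the 117 of 1 µM to 54, the 8 of 12 h to 1 (24 without replicate 1) and the 808 of 10 µM to 481, and leaving out replicate 2 of the G mock took the 121 that differed between doses to 49.

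Responses at 12 h were set against those at 3 h for the 7 compounds with both times, each against its own mock, so time cannot be told apart from bracket. For PNO8 at 1 µM the response of AT1G53540 was higher at 12 h by 3.12 ± 0.52 (adjusted p = 0.000294), and those of GSTU25 (-3.35 ± 0.57, 0.000397), AT1G47400 (-2.92 ± 0.48, 0.000294) and UGT73B5 (-2.69 ± 0.46, 0.000436) were lower, among 6 higher and 22 lower (43 and 79 with the block). For uniconazole AT5G04010 was higher by 2.97 ± 0.57 (adjusted p = 0.0359), the 1 call (6 with the block). AT1G29660 was lower at 12 h than at 3 h only with the block: -1.62 ± 0.27 for propiconazole (adjusted p = 0.00934), -1.42 ± 0.27 for uniconazole (0.041) and -1.63 ± 0.27 for Brz220 (0.00889). limma called 0 without the block for propiconazole, paclobutrazol, prohexadione, Brz220 and Brz91 (288, 158, 184, 200 and 220 at unadjusted p under 0.05), and 5, 0, 0, 1 and 4 with it. Leaving out replicate 2 of the F2 mock took PNO8 from 28 to 13, and leaving out replicate 1 of the F1 mock took uniconazole from 1 to 0. The counts of 0 reached 4 for propiconazole without replicate 2 of the F1 mock, 2 for prohexadione without its replicate 1 at 12 h and 1 for Brz91 without replicate 1 of the F1 mock.

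Ibuprofen, an inhibitor of animal cyclooxygenases, and salicylic acid, a plant defence hormone, were given at 10 µM for 3 h. With ibuprofen GSTU25 (2.69 ± 0.40, adjusted p = 2.29e-05), AT1G47400 (2.48 ± 0.34, 2.68e-06) and GSTU22 (2.05 ± 0.32, 7.51e-05) rose. AT3G49960 (-2.13 ± 0.42, 0.00485), XTH26 (-1.79 ± 0.37, 0.00748) and EXPA8 (-1.49 ± 0.34, 0.0274) fell. With salicylic acid UGT76B1, a defence glycosyltransferase (4.43 ± 0.30, adjusted p = 3.04e-18), AT1G19960 (4.40 ± 0.36, 1.6e-14), AT5G03350 (3.97 ± 0.44, 7.63e-10), GSTU25 (3.52 ± 0.40), the glutaredoxin gene GRX480 (2.04 ± 0.31) and SAG101 (1.07 ± 0.31, 0.0385) rose. AT4G22610 (-2.19 ± 0.36, adjusted p = 1.32e-05), AT3G49960 (-1.95 ± 0.42, 0.00174) and XTH26 (-1.93 ± 0.37, 0.000247) fell. All 3 measured salicylate genes rose with salicylic acid (3 adjusted over the list alone; list adjusted p = 9.58e-05, 0.00158 with the block). Of 8 detoxification genes 3 rose with salicylic acid (6 adjusted over the list alone; list adjusted p = 0.00811, 0.0492 with the block) and 2 with ibuprofen (3 adjusted over the list alone; 0.0199, 0.0767 with the block). These became 0.0923 without replicate 2 of salicylic acid and 0.161 without replicate 1 of the F1 mock. The list of protein folding genes of the endoplasmic reticulum had adjusted p = 0.285 with an estimated correlation for salicylic acid, 0.0362 with the block and 0.0156 after quantile normalization. limma called 27 higher and 15 lower probe sets with ibuprofen (196 and 198 with the block; 129 and 110 after quantile normalization) and 367 and 92 with salicylic acid (959 and 833; 848 and 637). Without replicate 2 of ibuprofen 42 fell to 13, and without replicate 2 of salicylic acid 459 fell to 231.

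The mock groups gave the background between brackets with no compound. In the G mock PDF1.2, a plant defensin gene (2.93 ± 0.52, adjusted p = 0.000429), and AT4G33720 (2.89 ± 0.58, 0.00196) were higher than in the F1 mock. ICL, isocitrate lyase of the glyoxylate cycle (-6.60 ± 0.78, 1.47e-07), and AT2G47780 (-2.82 ± 0.53, 0.000982) were lower, among 91 higher and 23 lower probe sets (676 and 728 with the block; 512 and 454 after quantile normalization). Between the 12 h and the 3 h mocks of F2 and F1 limma called 0 (439 at unadjusted p under 0.05). With the block it called 3 higher and 34 lower (1 and 0 after quantile normalization without the block), among them AT1G73120 (-1.46 ± 0.24, adjusted p = 0.0071). The median of all probe sets differed by -0.144 here and by 0.007 after quantile normalization. Leaving out replicate 1 of the G mock took the 114 calls between the 3 h mocks to 36.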

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

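The tests in this part were all fixed before the values were seen. A response differed between times by a test of the difference for 28 probe sets with PNO8 at 1 µM and for 1 with uniconazole. With PNO8 121 probe sets had responses that differed between 10 µM and 1 µM. These differences also cross brackets with different mocks.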

How the results depend on the processing

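The rescaling of each array to one common 2% trimmed mean was chosen after seeing the data; the other alternatives were planned. The cause was not tested for the changes below, except that the 6 scaling levels widen the spread within groups when no block is used, and the median residual SD was 0.209 with the block against 0.312 without. Of 423 named gene values 1 reversed: XTH19 with salicylic acid was 0.15 without replicate 1 of the F1 mock, against -0.88 with all arrays, which had not passed the threshold; without replicate 2 it was -1.92 and passed. Of 245 named gene values past the threshold, 106 missed it without some array. With 2 arrays per group, leaving 1 out leaves a lone array that is assumed to vary like the others. These fits had no block, so a comparison that lost an array also crossed the scaling levels unevenly. Replicate 1 minus replicate 2 had a median of 0.282 log2 units in F1, -0.393 in F2 and 0.0935 in G. A changed count or a lost call can therefore come from the scaling as well as from the array left out. Dim probe sets lie close to the background and limit what can be seen.

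With the replicate block the counts were 33 for propiconazole at 3 h, 79 for propiconazole at 12 h, 17 for uniconazole at 3 h, 409 for uniconazole at 12 h, 8 for paclobutrazol at 3 h, 17 for paclobutrazol at 12 h, 51 for prohexadione at 3 h, 11 for prohexadione at 12 h, 344 for 2,4,6T at 3 h, 41 for PCIB at 3 h, 2387 for TIBA at 3 h, 38 for NPA at 3 h, 17 for Brz220 at 3 h, 125 for Brz220 at 12 h, 39 for Brz91 at 3 h, 89 for Brz91 at 12 h, 9 for Brz220 3 µM at 3 h, 4765 for AgNO3 at 3 h, 97 for AVG at 3 h, 9425 for CHX at 3 h, 300 for MG132 at 3 h, 379 for PNO8 1 µM at 3 h, 2507 for PNO8 at 3 h, 394 for ibuprofen at 3 h, 1792 for salicylic acid at 3 h, 2 for propiconazole minus paclobutrazol at 3 h, 1 for propiconazole minus paclobutrazol at 12 h, 1 for uniconazole minus paclobutrazol at 12 h, 71 for 2,4,6T minus PCIB at 3 h, 2004 for TIBA minus NPA at 3 h, 5 for propiconazole 12 h against 3 h, 6 for uniconazole 12 h against 3 h, 1 for Brz220 12 h against 3 h, 4 for Brz91 12 h against 3 h, 122 for PNO8 12 h against 3 h, 525 for PNO8 response minus 1 µM response at 3 h, 1404 for mock G at 3 h minus mock F1 at 3 h, 37 for mock F2 at 12 h minus mock F1 at 3 h. Differences between replicates 1 and 2 correlated between groups with a median r of 0.154 in F1 (-0.0943 to 0.31), 0.204 in F2 (0.0309 to 0.347) and 0.0086 in G (-0.00809 to 0.0163).

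After quantile normalization the counts were 16 for propiconazole at 3 h, 51 for propiconazole at 12 h, 10 for uniconazole at 3 h, 213 for uniconazole at 12 h, 5 for paclobutrazol at 3 h, 11 for paclobutrazol at 12 h, 24 for prohexadione at 3 h, 10 for prohexadione at 12 h, 291 for 2,4,6T at 3 h, 33 for PCIB at 3 h, 2185 for TIBA at 3 h, 20 for NPA at 3 h, 14 for Brz220 at 3 h, 78 for Brz220 at 12 h, 27 for Brz91 at 3 h, 39 for Brz91 at 12 h, 6 for Brz220 3 µM at 3 h, 4186 for AgNO3 at 3 h, 57 for AVG at 3 h, 9219 for CHX at 3 h, 163 for MG132 at 3 h, 299 for PNO8 1 µM at 3 h, 2382 for PNO8 at 3 h, 239 for ibuprofen at 3 h, 1485 for salicylic acid at 3 h, 1 for propiconazole minus paclobutrazol at 3 h, 1 for propiconazole minus paclobutrazol at 12 h, 1 for uniconazole minus paclobutrazol at 12 h, 1 for Brz220 minus Brz91 at 12 h, 53 for 2,4,6T minus PCIB at 3 h, 1687 for TIBA minus NPA at 3 h, 3 for propiconazole 12 h against 3 h, 2 for uniconazole 12 h against 3 h, 1 for Brz220 12 h against 3 h, 1 for Brz91 12 h against 3 h, 81 for PNO8 12 h against 3 h, 503 for PNO8 response minus 1 µM response at 3 h, 966 for mock G at 3 h minus mock F1 at 3 h, 1 for mock F2 at 12 h minus mock F1 at 3 h.

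After rescaling they were 19 for propiconazole at 3 h, 50 for propiconazole at 12 h, 9 for uniconazole at 3 h, 175 for uniconazole at 12 h, 4 for paclobutrazol at 3 h, 13 for paclobutrazol at 12 h, 14 for prohexadione at 3 h, 8 for prohexadione at 12 h, 260 for 2,4,6T at 3 h, 24 for PCIB at 3 h, 2055 for TIBA at 3 h, 25 for NPA at 3 h, 12 for Brz220 at 3 h, 81 for Brz220 at 12 h, 26 for Brz91 at 3 h, 39 for Brz91 at 12 h, 6 for Brz220 3 µM at 3 h, 4287 for AgNO3 at 3 h, 61 for AVG at 3 h, 174 for MG132 at 3 h, 267 for PNO8 1 µM at 3 h, 2117 for PNO8 at 3 h, 227 for ibuprofen at 3 h, 1443 for salicylic acid at 3 h, 1 for propiconazole minus paclobutrazol at 3 h, 1 for propiconazole minus paclobutrazol at 12 h, 1 for uniconazole minus paclobutrazol at 12 h, 45 for 2,4,6T minus PCIB at 3 h, 1669 for TIBA minus NPA at 3 h, 5 for propiconazole 12 h against 3 h, 2 for uniconazole 12 h against 3 h, 1 for Brz220 12 h against 3 h, 1 for Brz91 12 h against 3 h, 81 for PNO8 12 h against 3 h, 378 for PNO8 response minus 1 µM response at 3 h, 878 for mock G at 3 h minus mock F1 at 3 h, 1 for mock F2 at 12 h minus mock F1 at 3 h.

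Without a pseudocount they were 1 for prohexadione at 3 h, 1 for prohexadione at 12 h, 11 for NPA at 3 h, 10 for Brz220 3 µM at 3 h, 1 for PNO8 1 µM at 12 h, 1 for Brz220 minus Brz91 at 12 h, 0 for 2,4,6T minus PCIB at 3 h, 0 for uniconazole 12 h against 3 h, 65 for PNO8 response minus 1 µM response at 3 h. Without the filter they were 4 for uniconazole at 3 h, 4 for paclobutrazol at 3 h, 5 for Brz220 at 12 h, 1 for Brz220 3 µM at 3 h, 1 for daminozide at 3 h, 3 for 2,4,6T minus PCIB at 3 h, 2 for mock F2 at 12 h minus mock F1 at 3 h. With arrays of the bracket alone they were 2 for propiconazole at 3 h, 2 for paclobutrazol at 12 h, 6 for prohexadione at 12 h, 5 for Brz220 at 12 h, 2 for Brz91 at 3 h, 7 for Brz220 3 µM at 3 h, 4 for PNO8 1 µM at 12 h, 2911 for PNO8 at 3 h, 1 for 2,4,6T minus PCIB at 3 h, 0 for uniconazole 12 h against 3 h. With both 3 h mocks as the control they were 9 for propiconazole at 3 h, 6 for uniconazole at 3 h, 6 for paclobutrazol at 3 h, 19 for prohexadione at 3 h, 181 for 2,4,6T at 3 h, 24 for PCIB at 3 h, 17 for NPA at 3 h, 13 for Brz220 at 3 h, 11 for Brz220 3 µM at 3 h, 59 for AVG at 3 h, 96 for MG132 at 3 h, 1494 for PNO8 at 3 h, 193 for ibuprofen at 3 h, 5 for daminozide at 3 h, 763 for salicylic acid at 3 h.

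With 1 array left out the counts ran from 1 to 5 for propiconazole at 3 h, 3 to 9 for propiconazole at 12 h, 1 to 3 for uniconazole at 3 h, 3 to 12 for uniconazole at 12 h, 1 to 3 for paclobutrazol at 3 h, 1 to 6 for paclobutrazol at 12 h, 0 to 7 for prohexadione at 3 h, 0 to 4 for prohexadione at 12 h, 30 to 109 for 2,4,6T at 3 h, 0 to 9 for PCIB at 3 h, 600 to 960 for TIBA at 3 h, 1 to 9 for NPA at 3 h, 1 to 3 for Brz220 at 3 h, 2 to 11 for Brz220 at 12 h, 1 to 7 for Brz91 at 3 h, 3 to 6 for Brz91 at 12 h, 0 to 3 for Brz220 3 µM at 3 h, 1149 to 2088 for AgNO3 at 3 h, 4 to 20 for AVG at 3 h, 3988 to 6190 for CHX at 3 h, 8 to 61 for MG132 at 3 h, 54 to 121 for PNO8 1 µM at 3 h, 1 to 24 for PNO8 1 µM at 12 h, 481 to 827 for PNO8 at 3 h, 13 to 54 for ibuprofen at 3 h, 0 to 1 for daminozide at 3 h, 231 to 477 for salicylic acid at 3 h, 0 to 2 for propiconazole minus uniconazole at 12 h, 0 to 4 for uniconazole minus paclobutrazol at 12 h, 0 to 16 for 2,4,6T minus PCIB at 3 h, 494 to 813 for TIBA minus NPA at 3 h, 0 to 4 for propiconazole 12 h against 3 h, 0 to 1 for uniconazole 12 h against 3 h, 0 to 2 for prohexadione 12 h against 3 h, 0 to 1 for Brz91 12 h against 3 h, 13 to 34 for PNO8 12 h against 3 h, 49 to 135 for PNO8 response minus 1 µM response at 3 h, 36 to 122 for mock G at 3 h minus mock F1 at 3 h. All other counts stayed within 1.5 times under these alternatives.

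Adjusted p of list shifts that crossed the threshold were, with the replicate block, 0.00369 for cell wall expansion with propiconazole at 12 h, 0.00681 for cell wall expansion with uniconazole at 12 h, 0.00101 for cell wall expansion with paclobutrazol at 12 h, 0.0678 for salicylate with 2,4,6T at 3 h, 0.0622 for root hair markers with 2,4,6T at 3 h, 0.0678 for early stress response with TIBA at 3 h, 0.101 for root hair markers with TIBA at 3 h, 0.000387 for cell wall expansion with Brz220 at 12 h, 0.00681 for cell wall expansion with Brz91 at 12 h, 0.0358 for cell wall expansion with Brz220 3 µM at 3 h, 0.00555 for auxin response with CHX at 3 h, 0.0358 for proteasome with MG132 at 3 h, 0.0704 for oxidative stress with MG132 at 3 h, 0.0589 for heat shock with PNO8 1 µM at 12 h, 0.0767 for detoxification with ibuprofen at 3 h, 0.0362 for ER protein folding with salicylic acid at 3 h. After quantile normalization they were 0.0023 for cell wall expansion with propiconazole at 12 h, 0.00588 for cell wall expansion with uniconazole at 12 h, 0.000763 for cell wall expansion with paclobutrazol at 12 h, 0.0528 for early stress response with TIBA at 3 h, 0.0568 for root hair markers with TIBA at 3 h, 0.000148 for cell wall expansion with Brz220 at 12 h, 0.00588 for cell wall expansion with Brz91 at 12 h, 0.031 for cell wall expansion with Brz220 3 µM at 3 h, 0.00389 for auxin response with CHX at 3 h, 0.0159 for proteasome with MG132 at 3 h, 0.181 for oxidative stress with MG132 at 3 h, 0.091 for oxidative stress with PNO8 at 3 h, 0.0684 for detoxification with ibuprofen at 3 h, 0.0156 for ER protein folding with salicylic acid at 3 h. After rescaling they were 0.00463 for cell wall expansion with propiconazole at 12 h, 0.0093 for cell wall expansion with uniconazole at 12 h, 0.0018 for cell wall expansion with paclobutrazol at 12 h, 0.0588 for salicylate with 2,4,6T at 3 h, 0.0527 for early stress response with TIBA at 3 h, 0.0527 for root hair markers with TIBA at 3 h, 0.000262 for cell wall expansion with Brz220 at 12 h, 0.0093 for cell wall expansion with Brz91 at 12 h, 0.00383 for auxin response with CHX at 3 h, 0.0135 for proteasome with MG132 at 3 h, 0.167 for oxidative stress with MG132 at 3 h, 0.0857 for oxidative stress with PNO8 at 3 h, 0.0728 for detoxification with ibuprofen at 3 h, 0.0138 for ER protein folding with salicylic acid at 3 h, 0.0527 for detoxification with salicylic acid at 3 h. Without a pseudocount they were 0.0551 for salicylate with 2,4,6T at 3 h, 0.167 for oxidative stress with MG132 at 3 h, 0.0869 for heat shock with PNO8 1 µM at 12 h. Without the filter they were 0.0275 for auxin response with CHX at 3 h. With arrays of the bracket alone they were 0.0971 for salicylate with 2,4,6T at 3 h, 0.0535 for root hair markers with 2,4,6T at 3 h, 0.0999 for root hair markers with TIBA at 3 h, 0.0999 for ethylene response with AVG at 3 h, 0.0326 for auxin response with CHX at 3 h, 0.227 for heat shock with PNO8 1 µM at 12 h, 0.491 for early stress response with PNO8 at 3 h, 0.22 for detoxification with PNO8 at 3 h, 0.276 for oxidative stress with PNO8 at 3 h. With the preset correlation they were 2.69e-06 for cell wall expansion with propiconazole at 12 h, 1.28e-05 for cell wall expansion with uniconazole at 12 h, 7.44e-08 for cell wall expansion with paclobutrazol at 12 h, 3.29e-11 for cell wall expansion with Brz220 at 12 h, 1.61e-05 for cell wall expansion with Brz91 at 12 h, 0.0056 for cell wall expansion with Brz220 3 µM at 3 h, 5.64e-06 for auxin response with CHX at 3 h, 0.00149 for proteasome with MG132 at 3 h, 0.00855 for ER protein folding with salicylic acid at 3 h. With 1 array left out they ran from 0.0186 to 0.235 for salicylate with 2,4,6T at 3 h, 0.00539 to 0.253 for root hair markers with 2,4,6T at 3 h, 0.00938 to 0.362 for detoxification with PCIB at 3 h, 0.0162 to 0.0665 for early stress response with TIBA at 3 h, 0.0138 to 0.108 for root hair markers with TIBA at 3 h, 0.0249 to 0.14 for ethylene response with AVG at 3 h, 0.026 to 0.083 for auxin response with CHX at 3 h, 0.00898 to 0.258 for oxidative stress with MG132 at 3 h, 3.04e-05 to 0.43 for heat shock with PNO8 1 µM at 12 h, 0.0281 to 0.161 for detoxification with ibuprofen at 3 h, 0.000838 to 0.0923 for detoxification with salicylic acid at 3 h; the number of list shifts past the threshold ran from 19 to 41, against 33, and was 103 with the preset correlation.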

Other observations

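The test on root genes, the grouping of plastid genes and the interval of the shared-mock share were chosen only after the result was seen; the predictions on the shared mock and on mixed RNA were written down before. AT1G47400, the iron-deficiency peptide gene, was higher with propiconazole (2.197 ± 0.34), Brz91 (2.29 ± 0.34), MG132 (2.46 ± 0.34), PNO8 at 1 µM (2.61 ± 0.34) and ibuprofen (2.48 ± 0.34) at 3 h, all against the same 2 mock arrays; differences between these compounds were not tested. The 69 measured genes encoded by the plastid genome, a group formed after the data were seen, had a median of -0.505 with CHX, where 16 were lower (37 with the block), but did not stand apart from other genes (camera adjusted p = 0.989; 0.988 with the block), and the median of all probe sets was -0.214. Of lists with at least 1 measured member, photosynthesis, carbon starvation, circadian clock, flavonoid pathway, glucosinolate and cell cycle had no shift past the threshold with any compound when the correlation was estimated, with or without the block. They had 9, 4, 1 (GI), 6, 2 and 3 measured members in this order, so the shorter lists say little about their processes. With the preset correlation some passed, such as carbon starvation with Brz91 at 12 h (adjusted p = 0.000182) and flavonoid pathway with AVG (0.00134).

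Root hair genes (9 measured and chosen because they fell, among them EXPA7, EXPA18, XTH26 and peroxidase genes) were lower after several compounds, with medians of -1.73 for 2,4,6T, -2.85 for TIBA, -3.5 for AgNO3, -2.14 for PNO8 at 10 µM, -1.5 for ibuprofen, -1.39 for salicylic acid, -1.26 for CHX and -1.06 for MG132. If less root tissue were the whole cause, other root genes would be lower by about as much; of 61 root genes first written down from general knowledge after the pattern was seen, 28 were measured. The 28 include 4 peroxidase genes that are also among the 9. The medians of the 28 were -0.201 for 2,4,6T, -0.629 for TIBA, -0.208 for MG132, -0.391 for PNO8 at 10 µM and -0.233 for ibuprofen. They lay above both the 9 genes and EXPA7 and EXPA18 alone, which were fixed before the data (medians -1.34, -2.07, -1.02, -1.81 and -0.924), by more than the SD of the 28 (0.679 to 1.34). This argues against root loss as the whole cause there. With the block 7, 14, 7, 9 and 5 of the 28 were lower, of which the 4 shared genes supplied 4, 4, 3, 4 and 4. Of the 24 others 3, 10, 4, 5 and 1 were lower, so root loss stays open as a contribution. For AgNO3 and salicylic acid (medians of the 28 -1.2 and -0.46, with 18 and 8 lower) root loss cannot be told apart from a change in root hairs, since EXPA7 and EXPA18 (-2.21 and -1) lie within the SD of the 28 (1.5 and 0.634). Without the 4 shared genes the medians were -1.04 and -0.349 (SD 1.02 and 0.508), and EXPA7 and EXPA18 lay lower by more than the SD. The outcome for these 2 compounds thus depends on the 4 shared genes. For CHX the 28 were lower by as much as the 9 (-1.33, with 20 lower). With the block 6154 probe sets of any kind were lower with CHX, so this fall does not single out root tissue. PYK10, among the 28, was not lower with these compounds: 0.0752 with AgNO3, 0.186 with salicylic acid and 0.155 with CHX. It is 1 gene, while 18, 8 and 20 of the 28 were lower, so it does not decide the cause. The gap was first judged on the 9 genes alone, which also set AgNO3 and salicylic acid apart, and earlier on a set of 5 other root genes picked with their values in view and a set of 24 that left out 4 peroxidase genes of the pattern.

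Against the same F1 mock, 14 probe sets changed the same way with the block in at least 9 of 18 comparisons, which may come from mock arrays that are out of place. Of these 6 also differed the same way between the G and F1 mocks (42.9%, exact binomial 95% interval 17.7% to 71.1%), among them AT2G33490, at 8.07 in the F1 mock, 9.45 in the G mock and 8.99 in the F2 mock. AT2G33490 changed in 16 of the 18 comparisons, and its lowest treated group in F1 stood at 8.98. The prediction written beforehand, at least 50% if the mock were the cause, was not met. The interval, added after that was seen, covers 50%. It takes the 14 as independent, though all rest on the same mock arrays, so its width cannot be relied on. For 6 of the 14 (not the same 6) the F1 mock lay outside all treated groups of its bracket. The mock cannot be told apart from shared responses for these 14 as a set.

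AT1G19960 and AT5G03350 were higher with both prohexadione (AT5G03350 only with the block) and salicylic acid, which might come from RNA of salicylic acid treated seedlings mixed into the prohexadione samples. Their levels at 3 h would need 18% and 20% of such RNA. The 87 other probe sets raised by salicylic acid implied a median of 3.23% at 3 h (25th to 75th percentile 0.228% to 6.58%), below 8.9%, the bound set beforehand. This argues against mixed RNA as the cause of these levels at 3 h, while a smaller share is not excluded. AT1G19960 and AT5G03350 were picked for high values with prohexadione, which can raise their implied shares and the bound. No share was computed at 12 h. Exposure of the seedlings to salicylic acid itself, and a shared response to both compounds, stay open and were not tested.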
